A study of Mus musculus with 8 samples.

How the data were processed

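Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 4 cell populations sorted from mouse back skin. The labels list 8 samples, 2 per population. Bulge stem cells and hair germ cells came from resting (telogen) follicles at postnatal day 55. Basal and suprabasal transient amplifying cells (TACs, the dividing progeny of the stem cells) came from growing (anagen) follicles at postnatal day 30. Per the labels, the suprabasal TACs came from K14-H2BGFP mice and the other populations from Lgr5-eGFP-ires-CreER mice, and the sex of all samples was mixed.

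The authors deposited 4 peak lists, 1 per population, each called on 1 pooled alignment of both samples. Per the file headers, the authors called peaks with MACS 2.1.1.20160309 on paired-end fragments with all duplicates kept at that step, a q-value cutoff of 0.05, no control library, an effective genome size of 1.87e+09 and a local background window of 10 kb. Per the submitters' processing notes, Bowtie2 2.2.9, Picard and the mm10 build were also used. The name of the alignment in the file headers speaks of removed duplicates and a filter. A shift of the read ends for the transposase is not given in the sources used here; peaks were called from whole fragments, and positions near a peak edge carry that limit. Each deposited peak has a length in bp, the fragment coverage (pileup signal) at its summit, a −log10 p-value, a −log10 q-value and a fold enrichment over the local background, all computed by the authors' caller. The coverage is not scaled for depth. The names of both −log10 columns were damaged in the deposited files; they were told apart by their place in the caller's output. These scores are the authors' and were used only to describe, rank or filter peaks within a list, with 1 exception: in tests named below, coverage was scaled by the ratio of total fragments.

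Total fragments per pooled library, per the file headers, were 24065469 for the bulge, 11053351 for the hair germ, 30824845 for basal TACs and 47852893 for suprabasal TACs. A deeper library gives more significant peaks at the same openness, so by depth the hair germ list is the least sensitive. Depth was not the only difference: the suprabasal library, the deepest, gave 72153 peaks, fewer than the 75652 of the basal TAC library. The median fold enrichment per list was 7.48 in the bulge, 7.14 in the hair germ, 6.71 in basal and 4.79 in suprabasal TACs. Because each population has 1 pooled list, no spread between replicates could be computed and no p-value is given. Intervals are 95% intervals (Wilson for shares of peaks and sites, exact Clopper-Pearson for shares at gene lists and genes), and they cover counting error only.

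Peaks on the mitochondrial and Y chromosomes were left out of all comparisons. Peaks of 2 lists were called shared when they overlapped by at least 1 bp, and this was set beside the mean of 100 random placements of the second list on the same chromosomes. Overlapping peaks of the 4 lists were merged into sites, and each site was placed in 1 of 15 classes by the lists holding a peak in it. Gene positions came from a RefSeq table of the GRCm38.p6 assembly, the same build as mm10, with 21631 protein-coding genes used. The table gives neither strand nor exons. The planned assignment to transcription start sites was therefore replaced by the nearest protein-coding gene span within 100 kb (distance 0 inside a gene), and the planned promoter class by a distance within 1 kb of either gene end. Exons and introns were not separated. Of 114956 sites, 102821 were assigned to 16763 genes. Genome sequence was not used here, so a planned search for 27 transcription factor motifs was not run.

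Before the data were examined, 20 gene lists were written: bulge stem cell, hair germ, matrix (transcription factors and signals), inner root sheath, hair shaft and outer root sheath genes; WNT, BMP, TGF-beta, hedgehog and Notch pathway genes; cell cycle and interfollicular epidermis differentiation genes; and sebaceous gland, dermal, melanocyte, immune, endothelial, Merkel cell and widely expressed genes. Of 250 list entries 248 could be used; Krt74 and Krt85 were not analysed here. Some genes stand in several lists (Lef1, Cux1, Hoxc13 and Lgr5 among them), so lists are not independent. In each of 4 comparisons (hair germ against bulge, basal TAC against hair germ, suprabasal TAC against basal TAC, suprabasal TAC against bulge), a changed site was one held by only 1 of the 2 lists. The share of a gene list's changed sites found in only the first-named population was given as a percentile among 10000 random gene lists of the same size matched on the number of sites per gene. A list was taken to stand apart at or below percentile 2.5 or at or above percentile 97.5; among 80 values, 4 are expected there by chance. The percentile describes these peak lists and is not a test between conditions.

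Genes were named by a rule fixed before the data were examined: 18 chosen genes, the 10 genes with the largest difference in sites in each direction of each comparison (a subset is printed), and up to 4 members per list with the largest difference. Single sites were named only for the 18 chosen genes, as the changed site with the highest fold enrichment the authors gave.

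Alternatives planned in advance were a −log10 q-value of at least 10, the 56536 strongest peaks of every list (the number in the shortest list), the 20000 strongest peaks, reciprocal overlap of 50%, a summit inside the other peak, windows of 500 bp around summits, strict presence, removal of sites near gene ends, autosomes only, 2.5 kb instead of 1 kb around gene ends, a 20 kb limit or gene spans plus 10 kb for assignment, and unmatched random lists. Alternatives added after seeing the data were absence counted only where coverage scaled for depth would have reached the level at which the other list calls peaks (the 95th percentile of coverage among its peaks with −log10 q under 2), random lists of neighbouring genes, each list without its member with most changed sites, site classes without the hair germ list, and removal of a stretch around Cwc22. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9; overlaps were checked against bedtools 2.31.1. The list percentile was tested on simulated lists of 20 genes drawn from 16763 genes. With no effect, 6.5% of 200 simulated lists stood apart for hair germ against bulge, 5.0% for basal TAC against hair germ, 7.0% for suprabasal against basal TAC and 4.5% for suprabasal TAC against bulge. With the odds of a gain multiplied by 4, the shares standing apart above the random lists were 79.0%, 91.0%, 99.0% and 99.5% in the same order, and with the odds multiplied by 2 they were 29.0%, 49.5%, 63.0% and 70.5%. In the simulation the sites of a gene changed independently of each other. In the data they can change together: at Cux1, 32 sites were in basal TACs alone and 0 in the hair germ alone. The simulated shares can therefore be too high for the real lists.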

Results

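Accessible regions were compared along the hair follicle lineage, from the stem cells of the bulge to the hair germ that is the first to proliferate at the start of a hair cycle, and on to the basal and suprabasal TACs of the growing follicle. Bulge cells had been sorted as GFP+/CD34+ and hair germ cells as GFP+/CD34-, both positive for integrins α6 and β1. Basal TACs were high in integrin β1 and positive for P-cadherin, and suprabasal TACs were low in GFP and negative for integrin α6. The bulge list held 62333 peaks from 24065469 fragments, the hair germ list 56548 from 11053351, the basal TAC list 75652 from 30824845 and the suprabasal TAC list 72153 from 47852893. Each list pools 2 samples, so no value below has a replicate error. Median peak lengths were 718, 651, 687 and 639 bp in the same order, and the peaks covered 51.8, 42.8, 61.2 and 55.8 Mb.

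The 4 lists merged into 114956 sites. A peak was present in all 4 populations at 31420 sites, or 27.3% (95% interval 27.1 to 27.6). Of these common sites, whose median length was 1283.5 bp, 33.3% were within 1 kb of a gene end. Sites held only by telogen populations (bulge, hair germ or both) numbered 18246, or 15.9%, and only 3.12% of them were near a gene end. Sites held only by anagen populations (basal TAC, suprabasal TAC or both) numbered 46854, or 40.8%, with 4.42% near a gene end. Single populations held 7750 (bulge), 2701 (hair germ), 16635 (basal TAC) and 17842 (suprabasal TAC) sites of their own. With absence scaled for depth, a setting that also demands coverage at the calling level of the lists without a peak, these fell to 1862, 718, 4388 and 1480.

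**Figure D1:**
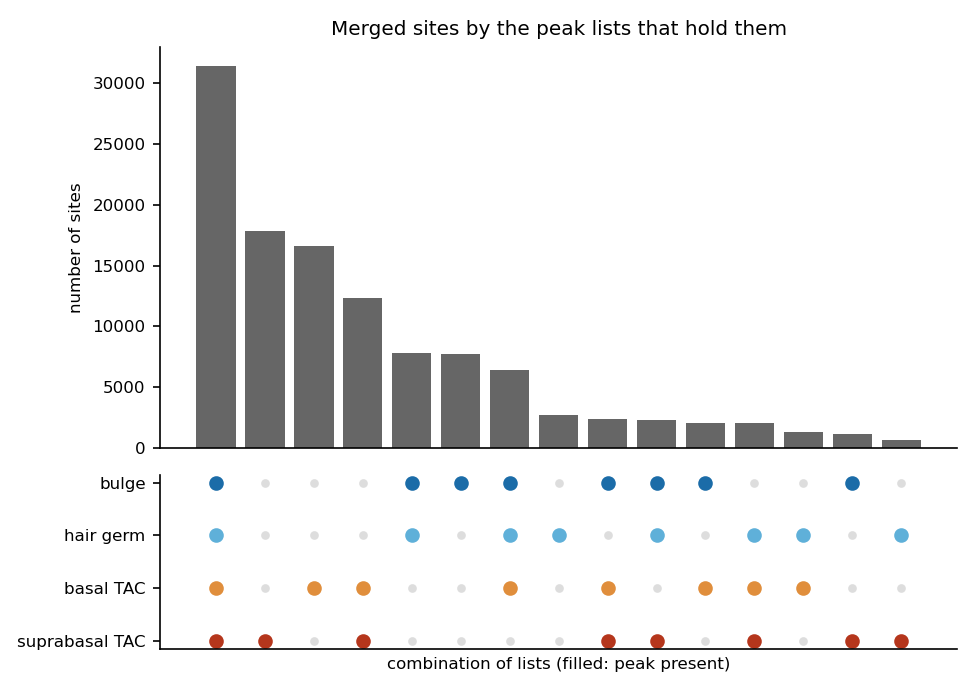
Number of merged sites (bars) in each of the 15 combinations of the 4 peak lists; filled dots mark the lists that hold a peak. The common class of 31420 sites is the tallest bar, followed by sites of suprabasal TACs alone (17842), of basal TACs alone (16635) and of both TAC populations (12377).

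By share of peaks, bulge and hair germ overlapped the most. Of hair germ peaks 87.5% (95% interval 87.3 to 87.8) overlapped a bulge peak, and of bulge peaks 77.8% overlapped a hair germ peak. Of bulge peaks 69.1% overlapped a basal TAC peak and 60.6% a suprabasal TAC peak. Of hair germ peaks 75.0% overlapped a basal TAC peak, and with a −log10 q-value of at least 10 this was 79.5%. At that setting 71.0% of bulge peaks overlapped a hair germ peak, but the hair germ list then held only 37457 peaks. The share of hair germ peaks in the bulge list was not computed there, so these values do not rank the pairs. Between the TAC populations, 64.6% of basal peaks overlapped a suprabasal peak and 69.0% of suprabasal peaks a basal one. Random placement gave between 3.39% and 4.799%. By base pairs, the Jaccard index (overlap divided by union) was 0.641 for bulge with hair germ, 0.465 for basal with suprabasal TAC, 0.421 for hair germ with basal TAC and 0.373 for bulge with suprabasal TAC. Stage and age at collection coincide here (postnatal day 55 against 30) and cannot be told apart.

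**Figure D2:**
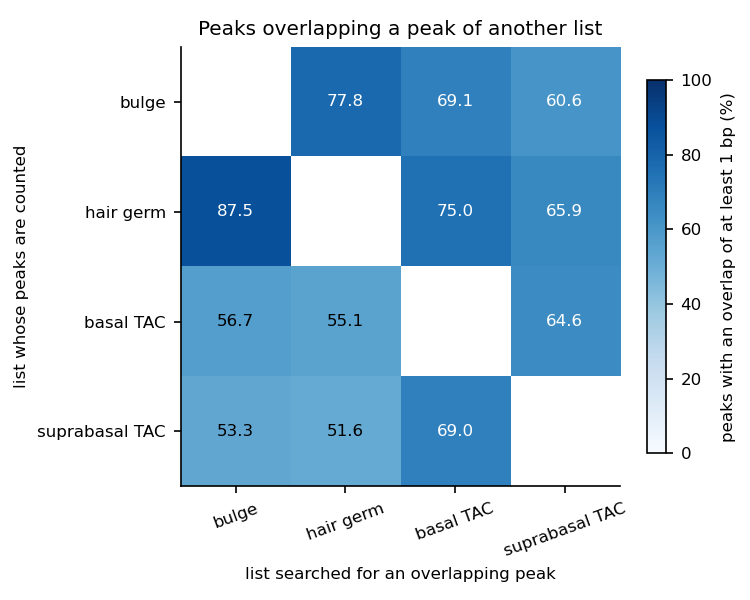
Share of peaks (%) of the list in each row that overlap a peak of the list in each column by at least 1 bp. The values run from 51.6% (suprabasal TAC peaks in the hair germ list) to 87.5% (hair germ peaks in the bulge list).

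The first comparison asked how chromatin differs between the stem cells of the bulge and the hair germ within telogen. Sites of bulge stem cell genes were held more often by the bulge list: only 26 of 125 changed sites (20.8%, 95% interval 14.1 to 29.0) were in the hair germ list alone, against a random median of 33.3% (percentile 1.91). Of the 20 members 14 had fewer sites in the hair germ, 3 had more and 3 had equal numbers. Nfib, a nuclear factor I gene, had 72 sites in the bulge and 49 in the hair germ, Nfatc1, a regulator of stem cell quiescence, 29 and 20, Sfrp1, a secreted WNT antagonist, 21 and 13, and Col17a1, a hemidesmosomal collagen, 16 and 9. Matrix genes lay above the random median of 33.3%, with 28 of 58 changed sites (48.3%) in the hair germ alone (percentile 98.5) and 30 in the bulge alone. Lef1, the transcription factor that acts with β-catenin, had 5 sites in the bulge and 10 in the hair germ, and Cux1 had 9 and 12. Among matrix genes, though, Gata3 had 16 and 11, and 9 members had more sites and 9 fewer. Hair shaft genes had 9 of 12 changed sites in the hair germ alone (75.0%, percentile 99.4), 4 of them at Selenbp1. Melanocyte genes had 0 of 11 (percentile 0.795), with 26 and 18 sites at Mitf.

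The hair germ library had fewer than 50% of the fragments of the bulge library, and 13400 sites were in the bulge list alone against 6754 in the hair germ list alone. None of these 4 lists stood apart when absence was scaled for depth, or when each list lost its member with most changed sites: the percentiles were then 27.2 and 11.96 for bulge stem cell genes, 82.0 and 96.8 for matrix genes, 87.1 and 95.5 for hair shaft genes and 13.6 and 4.31 for melanocyte genes. Scaling left 59, 18, 4 and 1 changed sites in these lists, with shares of 30.5%, 50%, 75% and 0% against random medians of 37.5%, 38.1%, 33.3% and 33.3%. With a −log10 q-value of at least 10 none of them stood apart either (percentiles 50.1, 85.7, 85.9 and 51.2 in the same order). Outside the lists, the genes with the most additional hair germ sites were Pde4d, a cAMP phosphodiesterase (24 in the bulge and 32 in the hair germ), Rapgef2 (17 and 24), Sdk1 (16 and 23) and Adk (9 and 15); at Pde4d and Rapgef2 the difference changed direction with a −log10 q-value of at least 10. Those with the most additional bulge sites after Nfib were Trabd2b (50 and 35), Slc6a6, a taurine transporter (28 and 14), Rbfox1 (22 and 9) and Tenm4 (56 and 43). The hair germ genes (44.8%, percentile 89.2) and the WNT (38.4%, 77.4), BMP (33.3%, 51.3), TGF-beta (47.2%, 95.6), hedgehog (27.7%, 22.7) and Notch (28.6%, 32.4) pathway genes lay within the central 95% of random lists. Hair germ genes lay outside it with equal numbers of peaks (percentile 98.86) and a −log10 q-value of at least 10 (98.9), and TGF-beta genes within 20 kb (98.1) and with gene spans plus 10 kb (97.59).

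The second comparison set basal TACs of anagen against the hair germ of telogen. Of all sites, 33482 were in basal TACs alone and 13448 in the hair germ alone, from libraries of 30824845 and 11053351 fragments. Bulge stem cell genes gained less than matched genes did. Of their 166 changed sites 89 were in basal TACs alone (53.6%, 95% interval 45.7 to 61.4), against a random median of 70.5% (percentile 0.06), and 13 of 20 members had fewer sites in basal TACs. The largest differences of single members were gains: Nfib had 49 sites in the hair germ and 64 in basal TACs, Tcf7l1 16 and 24, and Tcf7l2 27 and 35. Sox9, a stem cell transcription factor, had 12 and 7. At Nfib the difference turned to the other side with equal numbers of peaks taken from each list. Of matrix genes, 128 of 154 changed sites (83.1%) were in basal TACs alone (percentile 99.7), and 19 of 24 members had more sites. Cux1 had 12 in the hair germ and 44 in basal TACs, the largest gain of any gene; Lef1 had 10 and 18, Hoxc13, a regulator of hair keratins, 6 and 14, and Bmp2 5 and 13. The matrix percentile fell inside the central 95% without Cux1 (93.8), with depth scaling (91.6), equal numbers of peaks (89.7), a −log10 q-value of at least 10 (93.0) and unmatched random lists (92.4).

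Hair germ genes, which also include Cux1 and Lef1, had 81.3% of changed sites in basal TACs alone (percentile 95.8), within the central 95%. Ptch1, the hedgehog receptor, had 10 sites in the hair germ and 20 in basal TACs. Widely expressed genes stood low, with 8 of 20 changed sites in basal TACs alone (percentile 1.46), 9 of the other 12 at Ywhaz; without Ywhaz the percentile was 23.7. Cell cycle genes had 39 of 49 changed sites in basal TACs alone (percentile 83.6), with Cdk6 at 10 and 20 sites. Outer root sheath (61.8%, percentile 20.4), inner root sheath (82.8%, 86.2), hair shaft (63.3%, 17.8) and interfollicular epidermis differentiation genes (57.7%, 7.46) and the 5 pathway lists (percentiles 20.2 to 65.6) lay within the central range. The interfollicular list lay below it with equal numbers of peaks (percentile 0.385), with gene spans plus 10 kb (2.29) and without its member with most changed sites (1.53). Further genes with many added sites were Cacna2d3 (10 in the hair germ and 40 in basal TACs), Fhod3, an actin-assembling formin (18 and 48), Slit3, an axon guidance ligand (28 and 56), Tln2, a talin (4 and 31), and Robo1, a Slit receptor (8 and 33). Basal TACs had more sites of their own in total, from a deeper library, so these counts do not separate gains from depth. Fewer sites were found at Gmds (29 and 16), Aff1 (27 and 15), Tmem45a (16 and 5) and Zbtb16 (25 and 16); at Zbtb16 the difference changed direction with a −log10 q-value of at least 10.

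The third comparison set suprabasal against basal TACs, both of anagen. Inner root sheath, hair shaft and matrix genes had more sites in suprabasal TACs. Inner root sheath genes had 26 of 31 changed sites in suprabasal TACs alone (83.9%, 95% interval 66.3 to 94.5, percentile 99.97), and 10 of 11 members had more sites. Tgm3, a transglutaminase, had 9 sites in basal and 15 in suprabasal TACs, Gata3, an inner root sheath regulator, 12 and 17, and the keratin gene Krt27 1 and 3. Hair shaft genes had 31 of 38 (81.6%, percentile 99.9), with Hoxc13 at 14 and 19 sites, the desmoglein Dsg4 at 7 and 12, Krt36 at 0 and 3, and Krt83 at 1 and 4. Matrix genes had 109 of 165 (66.1%, percentile 99.97), with Trps1 at 18 and 32 and Lef1 at 18 and 27, while Cux1 had 44 and 39. Notch pathway genes had 39 of 54 (72.2%, percentile 99.7), and 10 of 12 members had more sites, among them Notch1 (9 and 14) and Notch2 (13 and 19). Interfollicular epidermis differentiation genes had 23 of 29 (79.3%, percentile 99.8), with Dsc1, a desmocollin, at 9 and 14. For all lists together, the random median lay between 44.9% and 50.0%.

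Outer root sheath genes had 5 of 19 changed sites in suprabasal TACs alone (26.3%, percentile 6.44), inside the central range, and were outside it with gene spans plus 10 kb (1.63). Hair germ (percentile 70.9), cell cycle (71.0) and widely expressed genes (94.55) and the other 4 pathway lists (31.3 to 95.45) were inside too. Bulge stem cell genes had 52 of 155 changed sites in suprabasal TACs alone (33.5%, percentile 2.97), just inside the central range. Lgr5, a stem cell marker, had 16 sites in basal and 7 in suprabasal TACs, Nfib 64 and 44, and Tcf7l1, a repressor of WNT targets, 24 and 16. The basal TACs came from Lgr5-eGFP-ires-CreER mice and the suprabasal TACs did not, so the allele at Lgr5 itself differs too. Further genes with more suprabasal sites were Foxp1 (53 and 74), Bach2 (32 and 52), Shank2 (8 and 27), Robo1 (33 and 52) and Cwc22 (4 and 30). At Cwc22 the median fold enrichment of the suprabasal-only sites was 2.15. As described below, this argues against separate open elements of usual contrast there, and extra copies of the stretch stay open. Fewer suprabasal sites were found at Rbms3 (55 and 27), Creb5 (50 and 26), Slit3 (56 and 33), Elmo1 (34 and 13) and Lrig1, a stem cell marker of the upper follicle (28 and 8). Mouse strain differs between these populations, so population and strain cannot be told apart. The basal list had peaks at 4 Y-linked genes described below and the suprabasal list at 0. A difference in the sex of the pooled mice cannot be told apart either. The hair shaft call was lost when sites were assigned to gene spans plus 10 kb (percentile 95.7), and the matrix and Notch calls with unmatched random lists (percentiles 97.4 and 96.7).

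The fourth comparison set the ends of the series, suprabasal TACs and bulge, against each other. Bulge stem cell genes had only 66 of 244 changed sites in suprabasal TACs alone (27.0%, 95% interval 21.6 to 33.1), against a random median of 56.7% (percentile 0), and 17 of 20 members had fewer sites. Nfatc1 had 29 in the bulge and 15 in suprabasal TACs, Sfrp1 21 and 5, and Lgr5 21 and 7. Matrix genes had 181 of 209 (86.6%, percentile 100), and 20 of 24 members had more sites. Lef1 had 5 in the bulge and 27 in suprabasal TACs, Hoxc13 5 and 19, Cux1 9 and 39, and Trps1 14 and 32. Inner root sheath genes had 42 of 49 (85.7%, percentile 98.96), and all 11 members had more sites. Hair shaft genes had 47 of 56 (83.9%, percentile 98.4) and Notch pathway genes 52 of 66 (78.8%, percentile 98.8). Hair germ genes had 90 of 123 (73.2%, percentile 97.7), 31 of them at Cux1, without which the percentile was 79.9. The hair shaft call was lost without Hoxc13 (percentile 90.5), within 20 kb (93.3) and with gene spans plus 10 kb (93.2), and the inner root sheath call with a −log10 q-value of at least 10 (97.2) and unmatched random lists (97.2), where the Notch call was lost too (91.7). Age and strain both differ here, and the peaks at Y-linked genes and the allele at Lgr5 differ as in the third comparison.

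Among other genes, Prlr, the prolactin receptor, had 27 sites in the bulge, 18 in the hair germ, 16 in basal and 2 in suprabasal TACs. Dpyd had 25, 14, 11 and 1, Hmcn1 33, 30, 28 and 9, and Zbtb16 31, 25, 16 and 9. In the other direction, Robo1 had 9, 8, 33 and 52, Baz2b 12, 11, 24 and 37, and Zfp618 6, 4, 14 and 29. Genes named by this count are long: the median span of the 64 named genes was 371 kb, against 23.1 kb for all 16763 genes with a site. The WNT (61.2%, percentile 76.3), BMP (61.2%, 67.1), TGF-beta (56.8%, 48.4) and hedgehog (55.2%, 42.3) pathway genes, the cell cycle (65.0%, 71.8), interfollicular epidermis differentiation (71.1%, 80.4), outer root sheath (40.6%, 9.32) and widely expressed genes (55.6%, 42.3) lay within the central 95%. Outer root sheath genes lay outside it with gene spans plus 10 kb (percentile 0.24) and WNT genes with depth scaling (97.64), where their share was 38.5% and the random median 23.4%. Within the WNT list, members moved apart: Lef1 and Znrf3 (10 and 25 sites) had more sites in suprabasal TACs, Sfrp1 and Lgr5 fewer.

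**Figure D3:**
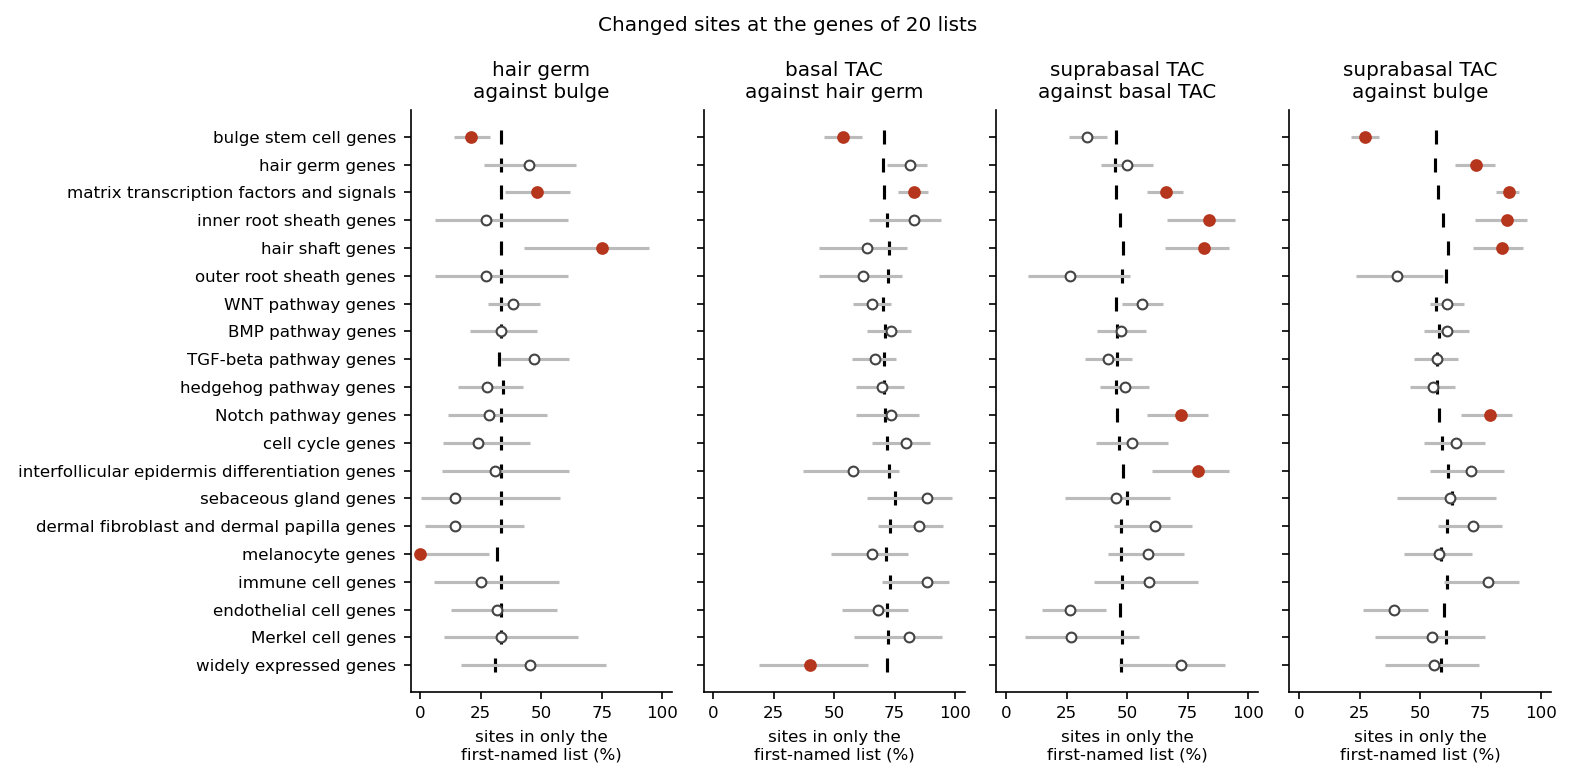
Share of changed sites (%) found in only the first-named population of each comparison, for 20 gene lists. Points are the shares (red: at or outside percentile 2.5 or 97.5 of 10000 matched random lists), grey lines exact 95% intervals and black ticks the median of the random lists; the number of red points per panel is 4, 3, 5 and 6.

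Markers of cell types outside the sorted lineage were looked at in the same way. Against the bulge, the suprabasal share was 62.5% for sebaceous gland genes (percentile 47.9), 72.0% for dermal genes (83.6), 57.7% for melanocyte genes (46.7), 78.1% for immune genes (89.4), 39.3% for endothelial genes (3.56) and 55% for Merkel cell genes (38.3). For suprabasal against basal TACs the endothelial share was 26.5% (percentile 2.78), also within the central 95%. Of its members 3 had more sites in suprabasal TACs, 5 fewer and 2 equal numbers. Tek had 11 sites in basal and 0 in suprabasal TACs and Emcn 8 and 0, while Pecam1 had 9 and 12. Melanocyte genes did not move together: against the bulge, 6 of 10 members had more sites in suprabasal TACs, 3 fewer and 1 equal numbers. Mitf had 26 sites in the bulge and 13 in suprabasal TACs, Dct 3 and 13, and Kit 1 and 7. For suprabasal against basal TACs the list was at percentile 78.6, and at 99.4 without Mitf, its member with most changed sites.

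Of the 18 genes chosen in advance 17 could be placed. Lef1 (chromosome 3, 131110297 to 131224357, mm10) had 5, 10, 18 and 27 sites from bulge to suprabasal TAC, Msx1 4, 6, 12 and 14, Msx2 10, 12, 13 and 16, and Hoxc13 5, 6, 14 and 19. Tmeff1, a TGF-beta target gene, had 1, 1, 4 and 7, Foxn1 3, 3, 5 and 7, Krt71 1, 1, 3 and 4, and Shh 4, 2, 6 and 9. Cd34, encoding the surface protein used for the bulge sort, had 9, 7, 6 and 6. Lgr5, at which the mice of all but the suprabasal list carried the GFP allele, had 21, 17, 16 and 7. Nfatc1 had 29, 20, 16 and 15, Sox9 10, 12, 7 and 7, and Krt15 3, 3, 2 and 2. Lhx2 (13, 13, 11 and 15), Cdh3, encoding P-cadherin (12, 10, 10 and 13), Tcf7l1 (18, 16, 24 and 16) and Gata3 (16, 11, 12 and 17) had no steady order, nor had Shh and Sox9.

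**Figure D4:**
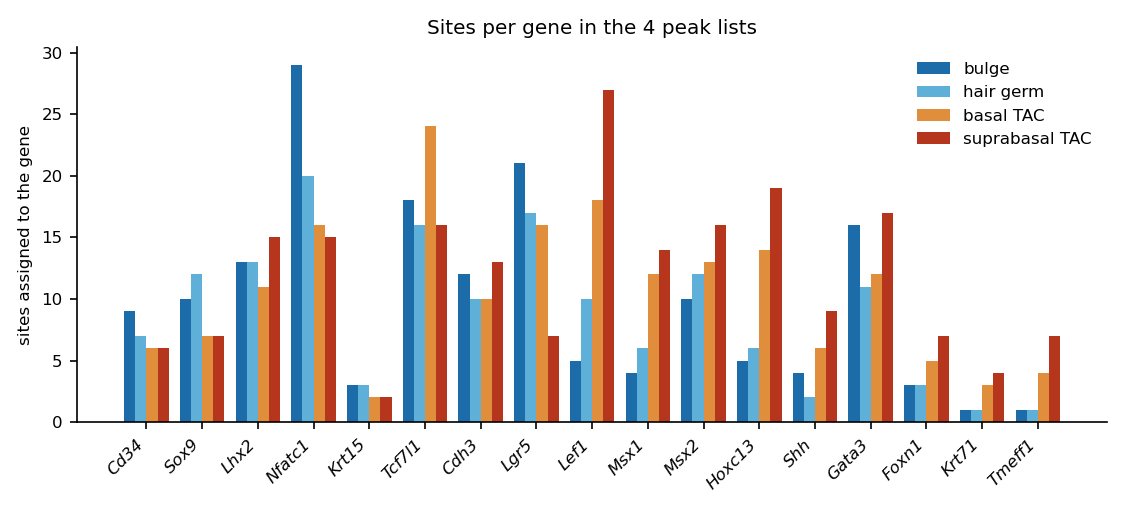
Number of sites assigned to each of 17 genes chosen in advance, in each of the 4 peak lists (bars). Lef1 runs from 5 sites in the bulge to 27 in suprabasal TACs, and Lgr5 from 21 to 7.

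At Lef1, a site on chromosome 3 at 131040069 to 131040903, outside the gene and 69.8 kb from it, was absent from the bulge list and present in the other 3, with a fold enrichment of 13.2 in suprabasal TACs. A site at 131065988 to 131066764 was held by both TAC lists only (fold enrichment 11.5 in basal TACs). At Shh, a site 28.9 kb outside the gene (chromosome 5, 28495572 to 28496505) was held by both TAC lists only, with a fold enrichment of 10.7 in basal TACs. Inside the span of Tmeff1, a site on chromosome 4 at 48625473 to 48626386 was likewise held by both TAC lists only (12.9 in basal TACs). At Lgr5, a site inside the gene span (chromosome 10, 115455531 to 115456686) was held by all lists except the suprabasal one, with a fold enrichment of 17.4 in the bulge. Bulge and hair germ cells were sorted as GFP+ from mice carrying GFP at Lgr5, so sites there may depend on the sort. At Cd34, a site 8.73 kb outside the gene (chromosome 1, 194929594 to 194930581) was held by the bulge and hair germ lists only (15.0 in the bulge), and at Nfatc1 so was a site inside the gene span (chromosome 18, 80617090 to 80618011, 9.86 in the bulge). Other sites picked by the same rule ran against these directions. At Hoxc13, a site 25.3 kb outside the gene was absent from basal TACs alone (13.8 in the hair germ). At Foxn1, a site inside the span was held by the bulge and hair germ lists only (7.74 in the bulge). At Tcf7l1, a site outside the gene was held by suprabasal TACs only (10.0).

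**Figure D5:**
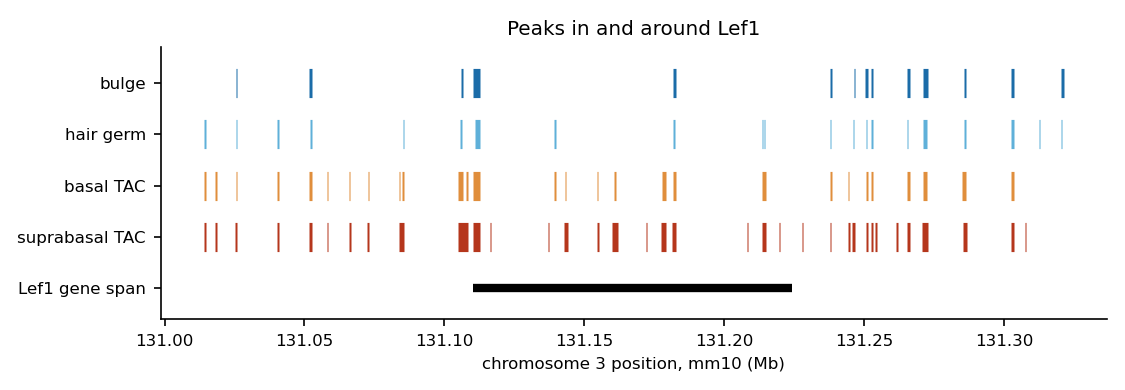
Peaks (coloured blocks, to scale) in and around Lef1 on chromosome 3 of mm10 (x axis in Mb) in the 4 peak lists, with the gene span in black and 100 kb on each side. The region holds 15 bulge, 21 hair germ, 28 basal TAC and 39 suprabasal TAC peaks, including peaks assigned to neighbouring genes.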

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

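All tests in this part were chosen after the results were seen, and each was replaced once after its value was seen; the first forms for the gene lists, for male cells and for extra copies of the Cwc22 stretch had gone with the explanation. Peaks left out of the comparisons were counted against the limit of 3 that a count of 0 allows. The Y chromosome carried 9 peaks in the bulge list, 7 in the hair germ list, 12 in the basal TAC list and 13 in the suprabasal TAC list. Mitochondrial DNA carried 4 peaks in the bulge list and 5 in the hair germ list, above that limit.

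The bulge, hair germ and basal TAC lists had peaks at the ends of all 4 of Kdm5d, Eif2s3y, Uty and Ddx3y, genes of the male-specific region chosen after their peaks were seen, and the suprabasal TAC list at 0 of 4; 12 of its 13 Y peaks lay beyond 90 Mb. The suprabasal library was the deepest of the 4, with 47852893 fragments. The hair germ list, from only 11053351, had a highest coverage of 8 (Kdm5d), 17 (Eif2s3y), 45 (Uty) and 31 (Ddx3y). Lower depth is therefore argued against as the source at these 4 genes. At the X chromosome counterparts of these genes the suprabasal list had peaks with a highest coverage of 199 (Kdm5c), 211 (Eif2s3x), 353 (Kdm6a) and 216 (Ddx3x). Few or no male cells in the suprabasal pool, where the labels give mixed sex, stays open and was not decided at Xist. Xist is an RNA gene active in female cells. Its strongest suprabasal peak had 0.782 times the coverage per fragment of the strongest peak in another list, the bulge. Without scaling for depth, the highest coverage there was 70 in the suprabasal list and 12 in the hair germ list (11053351 fragments). The basal TAC list had 0 peaks there. The same ratio of suprabasal TACs to the highest other list was taken at 700 X chromosome sites of all 4 lists. It ran from 0.165 (5th percentile) to 0.814 (95th), with a median of 0.383. No biological explanation was tested.

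Cwc22 on chromosome 2 had 27 suprabasal-only sites between 77869725 and 78024790, in a stretch where the bulge, hair germ, basal and suprabasal lists had 2, 1, 5 and 32 peaks. Separate open elements of usual contrast are argued against: the median fold enrichment of these sites was 2.15, below the lowest of 10000 draws (2.63) of suprabasal-only sites with similar coverage and as many suprabasal peaks within 5 kb. Of 1136 windows of 200 kb with at least 5 suprabasal-only sites, 4 had a median as low. Extra copies of the stretch in the suprabasal mice, a strain variant against the reference, stay open and undecided: the local background, on which the fold enrichment rests, was 2.90 times the median of the list, above the 99th percentile (2.76) of 3225 windows with at least 10 peaks, but 14 of 590 windows with at least 20 peaks were as high or higher. A broad open domain in suprabasal TACs would raise the local background too and was not tested.

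In hair germ against bulge, 13400 sites were in the bulge list alone, and the hair germ library was the shallower. Whether counting error at the lower depth is the only source could not be decided. Of 25777 bulge sites with a chance under 0.001 each of falling below the hair germ calling level of 17 after scaling, the hair germ list lacked 699. Counting error against that level gives 0.838. The model uses 1 flat level, while the caller measured each peak against its local background. A site with a high background can therefore be missed at lower depth despite high coverage. The 699 sites are 5.22% of the 13400. Over all bulge sites the same model gives 21304 missing, more than seen, so it does not describe the peak calls and depth stays open. For the 4 gene lists that stood apart lower depth cannot be told apart from a difference between the cells: scaling for depth left too few changed sites (59, 18, 4 and 1), and the 95% interval of the share excluded the random median in 0 lists. A difference between bulge and hair germ cells stays open, untested, beside differences in library quality that 1 pooled list per population cannot show.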

How the results depend on the processing

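Depth scaling, random lists of neighbouring genes, the omission of single members, of the hair germ list or of the Cwc22 stretch were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each population has 1 pooled list and no result comes from a test on samples. Of the values that answer a comparison, 71 stayed within their interval or within 1.5 times under an alternative and 73 did not. Of 18 list percentiles outside the central 95%, 5 stayed outside under every alternative run: bulge stem cell genes in basal TAC against hair germ (0.01 to 2.41) and in suprabasal TAC against bulge (0 to 0.13), matrix genes in suprabasal TAC against bulge (99.89 to 100), and, in suprabasal against basal TAC, inner root sheath (98.7 to 99.97) and interfollicular epidermis differentiation genes (99.3 to 99.96). Of the 62 inside, 12 moved outside under some alternative, as listed below. The planned motif search and its alternatives were not run. Where no reason is given, the cause was not tested.

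In the sharing of peaks, pairs are given in the order bulge in hair germ, bulge in basal TAC, bulge in suprabasal TAC, hair germ in basal TAC, hair germ in suprabasal TAC, basal in suprabasal TAC. Overlap of 50% of both peaks, stricter by construction, gave 68.5%, 54.5%, 45.7%, 58.7%, 49.6% and 51.3%. A summit inside the other peak gave 76.4%, 67.0%, 57.6%, 73.1%, 62.8% and 62.0%. Without peaks near gene ends the values were 73.6%, 62.7%, 52.4%, 69.1%, 57.6% and 58.7%. Equal numbers of peaks gave 82.1%, 63.1%, 57.1%, 65.7%, 59.3% and 65.7%. The 20000 strongest peaks gave 84.4%, 61.6%, 58.0%, 64.3% and 60.9% for the first 5 pairs. A −log10 q-value of at least 10 gave 71.0% for the first pair, 56.7% for the third, 79.5% for the fourth, 66.9% for the fifth and 59.2% for the last.

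Counts of peaks and sites moved by over 1.5 times as follows. The stricter q-value left 37457 hair germ peaks, 5194 sites in bulge and hair germ only, 927 in hair germ only and 10102 in suprabasal TAC only. Equal numbers of peaks gave 7071 sites in both TAC lists only, 4442 in hair germ only and 10641 in basal TAC only. The 20000 strongest peaks, fewer by construction, gave 9769 sites in all 4 lists, 3867 in bulge and hair germ only, 2216 in both TAC lists only, and 2264, 1528, 4329 and 5065 in bulge, hair germ, basal and suprabasal TAC alone. Strict presence gave 3421, 405, 10132 and 7111 for the same single lists. Depth scaling gave 1862, 718, 4388 and 1480 for these and 6007 for both TAC lists only. Without the hair germ list, the bulge alone held 15639 sites, since sites shared with the hair germ then count as its own. Shares near gene ends moved beyond their intervals: within 2.5 kb, a wider zone by construction, 24.9% of bulge, 27.0% of hair germ, 22.2% of basal TAC and 24.6% of suprabasal TAC peaks were near gene ends. With equal numbers of peaks the bulge, basal and suprabasal values were 20.4%, 19.8% and 20.9%.

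For hair germ against bulge, the lists apart numbered 2 with gene spans plus 10 kb (1 of the main 4, and TGF-beta genes), 1 with the stricter q-value (hair germ genes, and 0 of the main 4), 1 with unmatched random lists, 0 with depth scaling and 0 without the member with most changed sites, against 4. For basal TAC against hair germ the stricter q-value left 1 of 3. Unmatched random lists left 3 of 5 for suprabasal against basal TAC and 3 of 6 for suprabasal TAC against bulge. The stricter q-value moved bulge stem cell and melanocyte genes in hair germ against bulge across the middle, to percentiles 50.1 and 51.2. Further list calls were lost as follows. In hair germ against bulge, bulge stem cell genes fell inside with equal numbers of peaks (4.11) and unmatched random lists (13.75), matrix genes within 20 kb (91.6), with gene spans plus 10 kb (90), the stricter q-value (85.7) and unmatched lists (90.2), hair shaft genes with gene spans (95.8), equal numbers (97.0) and the stricter q-value (85.9), and melanocyte genes within 20 kb (2.88), with gene spans (3.47) and unmatched lists (4.35). In basal TAC against hair germ, widely expressed genes fell inside within 20 kb (4.46) and with the stricter q-value (6.64). In suprabasal TAC against bulge, hair germ genes did so within 20 kb (95.4), with gene spans (92.3), without sites near gene ends (96.6) and with unmatched lists (79.9).

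The lists that moved outside were as follows. In hair germ against bulge they were hair germ genes with equal numbers of peaks (98.86) and the stricter q-value (98.9), and TGF-beta genes within 20 kb (98.1) and with gene spans plus 10 kb (97.59). In basal TAC against hair germ they were interfollicular epidermis differentiation genes with gene spans (2.29), equal numbers (0.385) and without their member with most changed sites (1.53), dermal genes within 20 kb (98.4), and immune genes without such a member (97.67). In suprabasal against basal TAC they were hair germ genes with the stricter q-value (99.5), outer root sheath genes with gene spans (1.63) and without such a member (1.90), BMP genes with depth scaling (98.97), melanocyte genes without such a member (99.4) and endothelial genes with neighbouring genes drawn together (2.25). In suprabasal TAC against bulge they were outer root sheath genes with gene spans (0.24) and WNT genes with depth scaling (97.64).

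Some differences in sites per gene changed sign. The stricter q-value turned Pde4d and Rapgef2 in hair germ against bulge to -4 and -4, and Zbtb16 in basal TAC against hair germ to 6. Equal numbers of peaks turned Tenm2 in hair germ against bulge to 2 and, in basal TAC against hair germ, Arl15 to -4, Creb5 to -1, Efna5 to -5, Nfib to -11 and Tenm2 to -2. Depth scaling in suprabasal TAC against bulge turned Aopep to -1, Bach2 to -5, Nav2 to -2, Pde4d to -5, Shank2 to -1, Sorcs2 to -1 and Sox5 to -2. The hair germ list rests on the fewest fragments, 11053351, so depth limits which sites it can show.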

Other observations

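The gene families of this part were chosen after the data were seen, and 21 families in 4 comparisons were looked at, so about 5% of 84 values are expected outside the central 95% by chance; 10 were. Collagen and integrin genes had fewer sites in suprabasal TACs, the population sorted as negative for integrin α6, than in basal TACs. The 42 collagen genes had 265 sites in basal and 182 in suprabasal TACs, and 27.3% of changed sites were in suprabasal TACs alone (percentile 0.01 among matched random lists, random median 46.1%). The 25 integrin genes had 149 and 109 sites, with 23.7% (percentile 0.15). Against the bulge, the collagen genes were at percentile 0 and the integrin genes at 0.25. Laminin genes had 102 sites in basal and 84 in suprabasal TACs, at percentile 18.4, and were at 65.3 for suprabasal TACs against the bulge, both inside the central range. In hair germ against bulge they were at 97.8. No gene list stood apart in that comparison with depth scaling, which also limits the keratin-associated value below.

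Between the TAC populations, 2 families of WNT signalling and the Hoxd cluster (percentile 97.6) lay on the upper side. The Hoxd value rests on 6 sites in suprabasal TACs alone and 0 in basal TACs alone. The 19 WNT ligand genes had 100 sites in basal and 123 in suprabasal TACs (67.2% of changed sites in suprabasal TACs alone, percentile 98.9), and the 10 frizzled receptor genes 57 and 68 (70.4%, percentile 98.4). The WNT pathway list of the main comparisons was inside the central range there (56.3%, percentile 95.5), and against the bulge so were both families (80.6 and 83.7). Keratin-associated protein genes, which encode hair shaft proteins, had 13 sites in the bulge, 18 in the hair germ, 42 in basal and 44 in suprabasal TACs. Their percentile was 99.4 in hair germ against bulge, from 7 changed sites, and inside the central range in the other comparisons (90.3, 60.2 and 97.48). The 52 keratin genes as a whole had 103 sites in the hair germ and 114 in basal TACs (58.5%, percentile 1.09) and 128 in suprabasal TACs. Slit and Robo genes had 60 sites in the hair germ and 125 in basal TACs (82.8%, percentile 95.4), within the central range.

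Among the 83536 sites not held by all 4 lists, 65.0% had a peak in an unbroken run of lists that reached 1 end of the order bulge, hair germ, basal TAC, suprabasal TAC. The other 11 of the 12 possible orders gave 20.9% to 59.3%. The highest was the order by total fragments, which is the lineage order with bulge and hair germ exchanged. The lead over it rests on sites of a single list: the lineage order counts 7750 bulge-only sites, the other 2701 hair-germ-only sites. Such sites do not show which lists are neighbours. Sites absent only from the bulge (2053) count for the lineage order, those absent only from the hair germ (2406) for the other. The lead is therefore no evidence for the lineage order over the depth order. The lineage order was also highest with equal numbers of peaks (65.5%) and with the 20000 strongest peaks (64.4%). With a −log10 q-value of at least 10 it gave 60.6%, and the order with both TAC populations exchanged gave 62.6%.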
